A study of Mus musculus with 28 samples.

How the data were processed

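The series holds 28 samples of mouse C57Bl/6 cells, and their groups were taken from the sample labels. Bulk RNA was read in 18 libraries, single-cell RNA in 4 samples and Ty1 chromatin immunoprecipitation in 2. The 3 samples for acetylated histone H3 (H3K9/14ac) and 1 input sample were not analysed here. Per the labels' protocols, the HOXA9 and EYA1+HOXA9 lines were made from retrovirally transduced c-Kit+ bone marrow cells, sorted on fluorescent markers and replated in methylcellulose, and then kept in 5 µM benzarone or DMSO for 72 h. The MOZ-TIF2 and empty-vector cells were sorted on GFP and kept 4 days in cytokine medium. Poly(A) RNA was made into strand-specific libraries, per the labels' protocols.

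The bulk tables hold estimated counts per gene as the authors deposited them, not normalized, and the submitters' processing notes name Salmon 0.13.0 without its role. The single-cell tables hold whole counts of unique molecular identifiers (UMIs) per gene and cell as deposited, made with Cell Ranger 3.0.0 and parted by hashtags, per the submitters' processing notes. These tables list part of the genes, 9448 for days 1 and 3 and 11662 for day 5, so totals and CPM are over the listed genes. The peak lists hold intervals without scores on GRCm38, and reads were aligned with Bowtie2, per the submitters' processing notes. All peak starts and ends lie on a 50 bp grid, so whether starts count from 0 or 1 is open by 1 bp, and positions are printed as counted from 1.

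Counts were analysed in R 4.3.3 with edgeR 4.0.16, separately for the c-Kit table (6 libraries) and the line table (12 libraries). Genes were kept by filterByExpr, which left 15224 and 13375 genes, and libraries were scaled by TMM. The quasi-likelihood F test was fitted over all groups of a table, two-sided, with Benjamini-Hochberg adjustment within each comparison and a threshold of 0.05. Comparisons were MOZ-TIF2 against fresh, MOZ-TIF2 against differentiated and differentiated against fresh cells, EYA1+HOXA9 against HOXA9 in DMSO and in benzarone, benzarone against DMSO in each line, and the interaction of line and benzarone. Group values are means and SD of counts scaled to a common library size with TMM factors (CPM). These p-values measure only the spread between samples, which may be technical replicates. A gene without counts in a group is given as a lower bound against a floor of 3 counts over the group (0.0423 CPM for MOZ-TIF2, 0.0602 for differentiated, 0.0976 for fresh, 0.0382 for HOXA9 in DMSO). Such floors and all counting intervals cover counting error only.

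A set of 30 gene lists for blood lineages, granule stages, cell cycle, stress, metabolism and the retinal determination network was written with the design before the data were examined, as were the comparisons, tests and alternatives. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry, and for each list calls were also adjusted over the list alone. Of these, 28 lists in the line table had enough measured genes. Genes named in the text come from a rule of the same date: some fixed in any case, such as Eya1, Hoxa9, Hoxa10 and Meis1, the 6 largest rises and 6 largest falls among called genes with a mean of at least 10 CPM in the higher group, no overlap between groups and an ordinary gene symbol, and the 4 called members of each list with the smallest p (2 where the list did not pass camera). In single cells the rule took the 6 largest ratios each way at 50 CPM and 20 UMIs, and up to 3 members of each list at 20 CPM. For peaks it took those within 50 kb of the retinal determination and of the HOXA and MEIS genes. Other genes named, such as those called only under another setting, were chosen after their values were seen.

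For single cells, UMIs were summed over the cells of each condition and given as CPM with exact Poisson intervals (95%). No cell had under 1000 UMIs or over 10% mitochondrial UMIs, so none was removed, no doublet caller was run and no clusters were used. Median UMIs per cell were 44761.5 and 42565 for benzarone and DMSO on day 1, 44743 for benzarone on day 3, and 19763 and 24575.5 on day 5. List medians were set against 10000 random lists of the same size matched on level in 20 bins. Each condition of days 1 and 3 was a single sample, and day 5 was 1 sample that holds benzarone and DMSO cells together, so no test across samples was possible.

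Peaks were counted as shared when they overlapped by at least 1 bp, and the overlap was compared with 1000 rotations. Genes were taken from the given RefSeq table of GRCm38.p6, which had coordinates for 14507 of the 15224 tested genes (95.3%). It gives no strand, so the planned distance to the transcription start was replaced by the distance to either gene end, within 5 kb (also 1 and 50 kb). Odds ratios come from the Fisher exact test, and from Mantel-Haenszel pooling for comparisons within 10 groups of like level.

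Alternatives were DESeq2 1.42.0 size factors and its Wald test, no low-count filter, only the compared groups in the fit, a replicate block, each library left out in turn, a mean of at least 10 CPM, other overlaps and distances of peaks, and other summaries of single cells. Replicate numbers paired the HOXA9 libraries, where same-numbered benzarone and DMSO libraries deviated together (correlations 0.28, 0.30 and 0.55), and not the other groups. The fits were tested on simulated counts with 200 changed genes, where the data gave 3602 and 4486 calls for MOZ-TIF2 against fresh and differentiated cells. The adjustment is stricter with fewer changed genes, so the shares recovered are not the power of the real comparisons. Of genes changed 2-fold and 4-fold, edgeR recovered 0% and 1% for MOZ-TIF2 against fresh and 0% and 30% against differentiated cells (15224 genes), 75% and 94% for the lines in DMSO, 67% and 96% for benzarone with EYA1 and 70% and 94% without it (13375 genes). Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 served for peaks, tables and plots, and data.table (version 1.17.8) for reading.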

Results

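The deposited data come from mouse C57Bl/6 blood cells and cover RNA in 18 bulk libraries, single-cell RNA in 4 samples and chromatin binding in 2 samples with a Ty1-tagged MOZ-TIF2, a fusion oncoprotein of acute myeloid leukaemia. The RNA groups were MOZ-TIF2 cells (n = 2), c-Kit+ bone marrow cells as isolated (fresh, n = 2), and c-Kit+ cells with an empty vector kept 4 days in cytokine medium (differentiated, n = 2). A second set held bone marrow lines transformed by HOXA9, or by EYA1 with HOXA9, each given 5 µM benzarone, an inhibitor of the EYA phosphatases, or the solvent DMSO for 72 h (n = 3 in each of the 4 groups). Library totals were 34463851 and 33010700 counts for MOZ-TIF2, 12397486 and 15550960 for fresh cells, and 23656631 and 34260108 for differentiated cells. The lines had 26340517 to 34606046 counts.

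The comparison of MOZ-TIF2 cells with fresh c-Kit+ cells asked which RNAs set the transformed cells apart from the marrow cells they derive from. MOZ-TIF2 cells held more RNA of Six4, a homeobox gene of the retinal determination network, and nearly no erythroid or B-lymphoid RNA, which the differentiated cells had also lost. Six4 stood at 63.0 ± 24.7 normalised counts (CPM, SD, n = 2) against 0.103 ± 0.0632 (log2 difference 9.25, edgeR adjusted p = 0.00146). Hoxa9, Hoxa10 and Meis1, homeobox genes of self-renewing progenitors, were higher by log2 3.92, 6.88 and 2.39. The stem and progenitor list as a whole went the other way, with 10 of 20 genes lower and 1 higher (median -2.04). Adjusted over the list alone it was 11 and 1 (camera adjusted p = 1.08e-08, and adjusted p = 0.0913 with an estimated correlation). Eya1 read 11.4 ± 5.94 against 2.77 ± 0.877 CPM and did not pass the test (2.04, adjusted p = 0.105), though it passed with DESeq2 (2.03) and with the other group left out of the fit (2.04). F7, the gene of coagulation factor VII, rose to 97.3 CPM from 3 counts over the fresh libraries, a ratio of 996 (counting interval 341 to 4830). All 17 erythroid genes fell, among them the carbonic anhydrase gene Car2 from 1931 to 4.51 CPM (-8.74), and camera gave an adjusted p of 2.13e-60 for the list (adjusted p = 0.0447 with an estimated correlation and 0.346 with that and the replicate block). All 14 B-lymphoid genes fell as well, including the B cell receptor chain Cd79a (-11.6) and the surrogate light chain Vpreb1 (-8.22; camera adjusted p = 2.53e-48, adjusted p = 0.0258 with an estimated correlation and 0.259 with that and the block). Car1 and Aqp1, erythroid genes, had no counts in MOZ-TIF2 cells and were at least 27400-fold and 15100-fold lower, against a floor of 3 counts over the group. Of 12 megakaryocyte genes 11 fell, and 12 when adjusted over the list alone (camera adjusted p = 3.92e-16, and adjusted p = 0.0913 with an estimated correlation). The platelet genes Pf4 (-7.29), Gp1ba (-7.59) and Itga2b (-7.93) were among these. Of 25 monocyte and macrophage genes 13 fell and 2 rose, or 14 and 3 adjusted over the list alone (camera adjusted p = 1.94e-09, and adjusted p = 0.201 with an estimated correlation), and the complement gene C1qa was at least 4600-fold lower.

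Cholesterol synthesis and glycolysis genes moved the other way in the same comparison. All 20 cholesterol synthesis genes rose in MOZ-TIF2 cells, as most did in differentiated cells, with a median log2 difference of 3.13 (camera adjusted p = 4.83e-31, adjusted p = 0.0447 with an estimated correlation and 0.259 with that and the block). Mvd, an enzyme of the mevalonate pathway, was 14.6-fold higher than its 8.14 ± 0.805 CPM in fresh cells (3.86), the sterol demethylase gene Msmo1 rose by 3.23 and the sterol sensor partner Insig1 by 3.19. Of 17 glycolysis and hypoxia genes 10 rose and none fell, or 12 adjusted over the list alone (camera adjusted p = 2.69e-08, and adjusted p = 0.385 with an estimated correlation). The glucose transporter Slc2a1 rose by 4.29 and the mitophagy gene Bnip3 by 4.36. Xbp1, a transcription factor of the unfolded protein response, rose by 3.11. Of its 20 list members 9 were higher and 1 lower, or 12 and 2 adjusted over the list alone (camera adjusted p = 9.22e-05, and adjusted p = 0.201 with an estimated correlation). Jun, an immediate early gene that cell handling raises, fell from 570 to 16.7 CPM (-5.09) with 9 of 20 such genes, or 12 adjusted over the list alone (camera adjusted p = 8.61e-06, and adjusted p = 0.51 with an estimated correlation). The retinal determination list as a whole (9 measured) had 2 genes higher and 3 lower, or 4 and 3 adjusted over the list alone (camera adjusted p = 0.358), and the HOXA and MEIS list (16 measured) 5 and 2, or 7 and 4 (camera adjusted p = 0.363). edgeR called 3602 of 15224 genes, 1718 higher and 1884 lower, and 16 of 30 lists passed camera. The count rested on the fresh libraries, at 374 without replicate 1 and 451 without replicate 2, and it was 2094 with the replicate number as a block. Without either fresh library Hoxa9 (4.28 and 3.62), Hoxa10 (7.03 and 6.71) and Meis1 (2.81 and 2.04) were no longer called. Hoxa10 was also not called with that block (7.0) or without MOZ-TIF2 replicate 1 (6.25), and Six4 read 9.95 without fresh replicate 1.

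**Figure D1:**
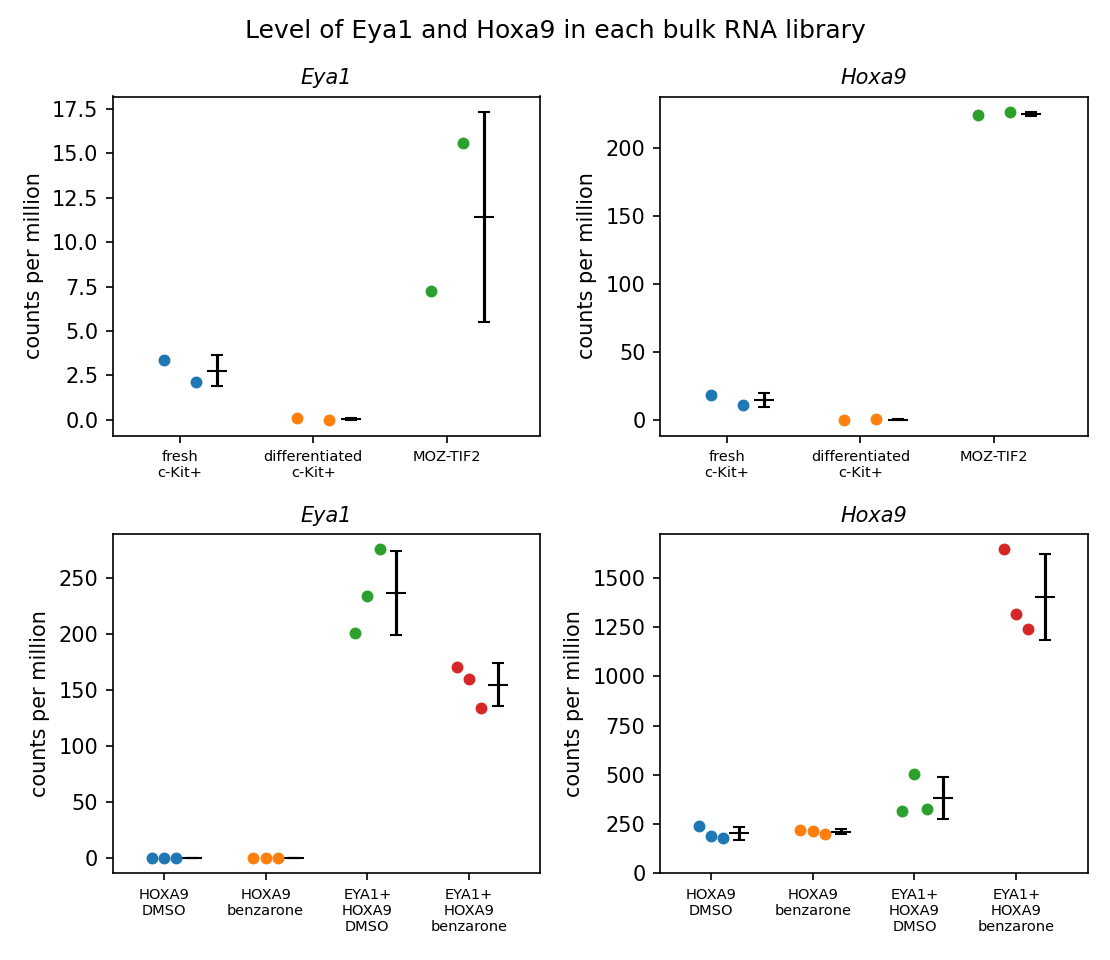
Level of Eya1 and Hoxa9 (CPM, linear axes) in each bulk RNA library, with 1 point per library and a bar for the group mean ± SD beside the points. Both MOZ-TIF2 points for Hoxa9 lie near the mean of 225 CPM, and Hoxa9 in EYA1+HOXA9 cells has a mean of 1402 CPM in benzarone against 382 CPM in DMSO.

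Set against the differentiated cells, the comparison asked how MOZ-TIF2 cells differ from cells of the same source that had matured in culture. The differentiated cells carried mast cell RNA and the MOZ-TIF2 cells granulocyte progenitor RNA. Against fresh cells the primary granule list did not pass (camera adjusted p = 0.422), with 2 genes higher in MOZ-TIF2 cells and 2 lower, or 4 and 2 adjusted over the list alone. Of 16 mast cell and basophil genes 15 were lower in MOZ-TIF2 cells and all 16 when adjusted over the list alone (camera adjusted p = 3.44e-19, and adjusted p = 0.0727 with an estimated correlation). The receptor gene Kit was far below its 4136 ± 188 CPM in differentiated cells (-6.89), and its transcription factor Gata2 was lower by log2 -9.63. Cebpe, Gfi1 and Cebpa, transcription factors of granulocyte formation, rose by 6.99, 4.21 and 2.92. Primary granule genes went with them, 9 of 14 higher and 1 lower, or 12 and 1 adjusted over the list alone (camera adjusted p = 5.6e-08, and adjusted p = 0.413 with an estimated correlation). The nucleolar gene Nop56 rose by 1.99. Ribosome synthesis and MYC target genes were higher for 14 of 20, or 18 adjusted over the list alone (camera adjusted p = 1.64e-06, and adjusted p = 0.483 with an estimated correlation). Replication genes were higher for 5 of 24, or 4 adjusted over the list alone, among them Cdc45 (2.17; camera adjusted p = 0.00148, and adjusted p = 0.63 with an estimated correlation). Mitosis genes were higher for 7 of 24, or 15 adjusted over the list alone, such as Bub1 (2.04) and Cenpe (1.78; camera adjusted p = 5.63e-05, and adjusted p = 0.514 with an estimated correlation). Against fresh cells neither the ribosome synthesis nor the mitosis list passed in MOZ-TIF2 cells (camera adjusted p = 0.689 for each). The replication list passed downward there (0.0192, and adjusted p = 0.864 with an estimated correlation). In differentiated against fresh cells the ribosome synthesis and mitosis medians were -1.55 and -1.14. The p53 targets Phlda3 (-5.14) and Zmat3 (-2.92) were lower with 9 of 21 list members, or 11 adjusted over the list alone (camera adjusted p = 0.00347, and adjusted p = 0.483 with an estimated correlation). Ahr, the aryl hydrocarbon receptor (-5.82), and its target Tiparp fell with 7 of 9 list members, or 8 adjusted over the list alone (camera adjusted p = 4e-05, and adjusted p = 0.253 with an estimated correlation). Cholesterol synthesis again ran higher in MOZ-TIF2 cells, with 9 of 20 genes up, or 11 adjusted over the list alone (camera adjusted p = 0.000242, and adjusted p = 0.384 with an estimated correlation). Examples were Fdps (2.87) and Mvd (2.34). Stem and progenitor genes were lower in MOZ-TIF2 cells for 10 of 20 and higher for 3, also adjusted over the list alone. Their median was -3.01 (camera adjusted p = 1.57e-05, and adjusted p = 0.253 with an estimated correlation). Other lineages were lower in MOZ-TIF2 cells, with 8 of 12 megakaryocyte (camera adjusted p = 2.27e-08) and 8 of 17 erythroid genes (2.11e-05). So were 10 of 25 monocyte genes (8.82e-07), with 1 higher, and 10 of 14 dendritic cell genes (0.000632). Immediate early genes fell for 8 of 20 (0.00901). With an estimated correlation these 5 lists gave adjusted p = 0.253, 0.413, 0.391, 0.483 and 0.626.

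The same comparison held Eya1 at 11.4 ± 5.94 against 0.0478 ± 0.0676 CPM (log2 difference 7.93, edgeR adjusted p = 0.00469). The differentiated value rests on 2 counts, so the ratio of 282 has a counting interval of 77.7 to 2330. Hoxa9 read 225 ± 1.48 against 0.352 ± 0.431 CPM (9.19), and Meis1 did not pass (-0.09, adjusted p = 0.876). Hoxa7 had no counts in differentiated cells and was at least 236-fold higher in MOZ-TIF2 cells by their mean. Their replicates 1 and 2 stood apart at 21.9 and 6.5 CPM. Without differentiated replicates 1 and 2 in turn the differences were 11.2 and 6.83 for Eya1 and 8.40 and 12.1 for Hoxa9, and Eya1 read 7.26 without MOZ-TIF2 replicate 2. The retinal determination list had 4 genes higher and 3 lower of 9 measured, the same counts adjusted over the list alone, with a median of -0.09 against a mean of 1.26 (camera adjusted p = 0.125, direction up). edgeR called 4486 genes, 2023 higher and 2463 lower in MOZ-TIF2 cells, and 2847 without differentiated replicate 1, while 20 of 30 lists passed camera.

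Differentiated against fresh cells shows what the empty-vector culture itself did. Part of what set MOZ-TIF2 apart from fresh cells was found here too. B-lymphoid genes fell for 13 of 14, also adjusted over the list alone (median -12.4, camera adjusted p = 1.11e-31, and adjusted p = 0.0733 with an estimated correlation). As a list they did not pass between MOZ-TIF2 and differentiated cells (camera adjusted p = 0.593), where 2 of them were higher and 1 lower in MOZ-TIF2 cells. Erythroid genes fell for 16 of 17, also adjusted over the list alone (median -8.77, camera adjusted p = 7.32e-28, and adjusted p = 0.119 with an estimated correlation). In MOZ-TIF2 cells 8 of 17 were lower than in differentiated cells, or 11 adjusted over the list alone (camera adjusted p = 2.11e-05, and adjusted p = 0.413 with an estimated correlation). Cholesterol synthesis genes rose for 18 of 20, or 19 adjusted over the list alone (median 1.85, camera adjusted p = 8.39e-11, and adjusted p = 0.189 with an estimated correlation). Mast cell genes rose, 13 of 16 with none lower and 13 adjusted over the list alone (camera adjusted p = 3.65e-13, and adjusted p = 0.119 with an estimated correlation). The mast cell protease gene Cma1 stood at 17270 ± 1100 against 0.388 ± 0.0273 CPM (15.4, edgeR adjusted p = 0.000804). The IgE receptor gene Fcer1a rose by 12.4. Primary granule genes fell for 10 of 14 and rose for 1, or 11 and 1 adjusted over the list alone (median -4.84, camera adjusted p = 2.46e-06, and adjusted p = 0.494 with an estimated correlation). Tph1, the enzyme of serotonin synthesis, and the tryptase gene Tpsab1 were without counts in fresh cells and at least 30600-fold and 29700-fold higher. Secondary granule and inflammatory granulocyte genes fell for 15 of 18, or 16 adjusted over the list alone, including S100a8 (-7.56) and S100a9 (-8.39; camera adjusted p = 5.14e-10, and adjusted p = 0.494 with an estimated correlation). Replication genes fell for 20 of 24, or 21 adjusted over the list alone, among them Ccne1 (-3.23) and Cdc45 (-2.11; camera adjusted p = 1.72e-06, and adjusted p = 0.625 with an estimated correlation). The p53 targets Zmat3 (4.24), Phlda3 (3.36) and Ccng1 (2.48) rose with 13 of 21 members and 1 fell, or 15 and 1 adjusted over the list alone (camera adjusted p = 0.000119, and adjusted p = 0.494 with an estimated correlation). Meis1 rose by 2.48 and Hoxa9 fell (-5.26, with -4.47 and -8.13 without differentiated replicates 1 and 2). edgeR called 6198 genes, 3195 higher and 3003 lower, but 1259 and 1555 without fresh replicates 1 and 2 and 3710 without differentiated replicate 1.

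In both comparisons 588 genes were higher in MOZ-TIF2 cells, among them Six4, Hoxa9 and Hoxa10, and 780 were lower. Independent lists of these sizes would share 228 and 305 genes, where simulated unchanged groups that share the MOZ-TIF2 libraries had 0 and at most 1 in common in 20 simulations. The comparisons share the MOZ-TIF2 libraries, so part of the excess may come from them, which the simulations, without real effects, do not measure. With a log2 difference over 1 in both, 509 genes were higher and 730 lower. The overlap rested on the fresh libraries. Without fresh replicates 1 and 2 in turn, a test chosen after seeing the data, 38 and 58 genes were higher in both and 186 and 202 lower, without Hoxa9 and Hoxa10.

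Binding of Ty1-tagged MOZ-TIF2 was read from the deposited peak lists, 3676 peaks in replicate 1 (median width 600 bp) and 4564 in replicate 2 (700 bp), on mouse GRCm38. Wide peaks lay on the HoxA cluster on chromosome 6. Replicate 2 held its widest peak there, 23800 bp from 52211352 to 52235151, and replicate 1 held peaks from 52215752 to 52226951, over Hoxa9, and from 52229052 to 52235101. Meis1 on chromosome 11 carried a peak from 19013852 to 19020001 in replicate 1. A peak found in both replicates lay within 50 kb of 14 of 16 HOXA and MEIS genes and 3 of 13 retinal determination genes (none of them Eya1), against 6488 of 14507 tested genes (44.7%). Of the 14 genes 8 lie in the HoxA cluster and share its peaks. Of the replicate 1 peaks 3303 overlapped a replicate 2 peak (89.9%, 95% Wilson interval 88.8 to 90.8), where 1000 rotations of the peaks gave a mean of 14 and at most 29. The antibody catalogue number that the label gives for replicate 2 is that of the acetyl-histone antibody, so which antibody made this list is unsure.

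**Figure D2:**
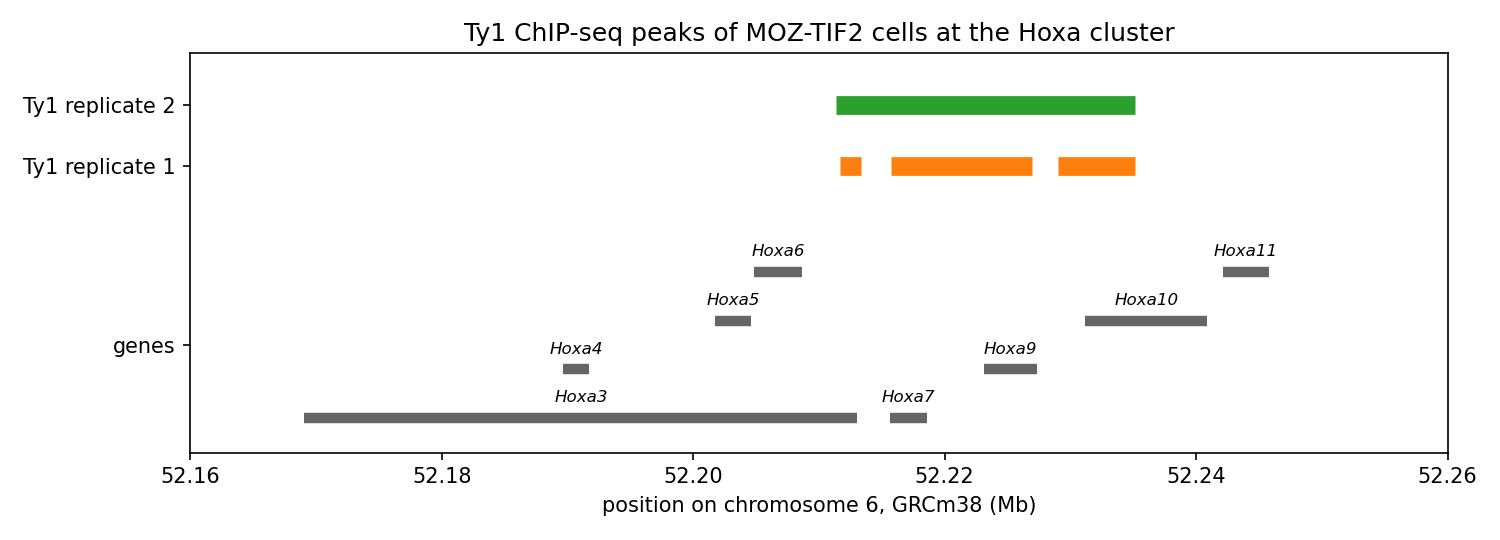
Map of the HoxA cluster on chromosome 6 of GRCm38 (position in Mb) with the peak intervals of both Ty1 replicates above the spans of the genes. The replicate 2 interval of 23800 bp covers the region where replicate 1 has intervals of 11200 bp and 6050 bp.

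Genes higher in MOZ-TIF2 than in fresh cells had such a shared peak within 5 kb of a gene end more often than other tested genes, 641 of 1660 (38.6%) against 2999 of 12847 (23.3%; odds ratio 2.07, interval 1.86 to 2.30, two-sided Fisher exact p = 1.97e-38). Genes lower in MOZ-TIF2 cells had one less often, 173 of 1837 (9.42%; odds ratio 0.276, interval 0.235 to 0.324). Six4, Hoxa10, Hoxa9 and the RNA-binding gene Igf2bp3 were among the higher genes with a peak. Compared within 10 groups of genes of like level in MOZ-TIF2 cells, the odds ratio was 0.992 (0.879 to 1.12) for the higher genes and 0.913 (0.76 to 1.1) for the lower genes. With peaks found in replicate 1 alone it was 1.01 for the higher genes over all tested genes and 0.714 (0.527 to 0.966) within like levels. With peaks found in replicate 2 alone it was 1.2 (1.01 to 1.41) and 0.866 (0.732 to 1.02). Against differentiated cells both differences were weaker. Of the genes higher in MOZ-TIF2 cells 31.2% had a shared peak, against 24.1% of other tested genes (odds ratio 1.43, interval 1.29 to 1.59). Of the lower genes 17.5% had one (odds ratio 0.586, interval 0.524 to 0.656). Within like levels in MOZ-TIF2 cells these odds ratios were 0.9 (0.801 to 1.01) and 0.889 (0.784 to 1.01). Genes are not independent replicates.

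EYA1+HOXA9 against HOXA9 cells in DMSO asked how cells with EYA1 and HOXA9 differ from cells with HOXA9 alone. EYA1 goes with the line here, so its effect cannot be told from other differences between the lines. Eya1, the introduced gene, was at 237 ± 37.4 CPM (SD, n = 3) and without counts in HOXA9 cells, at least 6210-fold higher. Hoxa9 rose from 203 ± 33.1 to 382 ± 108 CPM (log2 difference 0.92, edgeR adjusted p = 0.00477) and Six4 by 2.29. Both lines carry a HOXA9 vector, whose reads cannot be told from those of the gene. Of 7 retinal determination genes measured 3 rose and none fell, also adjusted over the list alone (camera adjusted p = 1.22e-09, adjusted p = 0.0203 with an estimated correlation and 0.0981 with that and the replicate number as a block). That list holds the introduced Eya1. Without Eya1, a test chosen after seeing the data, 2 of 6 rose, also adjusted over the list alone (camera adjusted p = 0.0235, and adjusted p = 0.443 with an estimated correlation). Secondary granule genes fell for 9 of 18 and rose for 1, or 11 and 1 adjusted over the list alone (camera adjusted p = 1.39e-06, and adjusted p = 0.443 with an estimated correlation). The chitinase-like gene Chil3 read 4.23 ± 0.118 against 311 ± 73.7 CPM (-6.20), S100a9 was at -4.44 and the granule gene Wfdc21 at -2.67. Cholesterol synthesis genes fell for 17 of 20, and 17 adjusted over the list alone, among them Fdps (-1.11), Cyp51 (-1.13) and Mvk (-1.01; camera adjusted p = 1.5e-09, and adjusted p = 0.443 with an estimated correlation). Mitosis genes fell for 11 of 24, or 15 adjusted over the list alone, by small steps such as -0.79 for Kif23 and -0.78 for Bub1 (camera adjusted p = 0.000672, and adjusted p = 0.443 with an estimated correlation). Oxidative stress genes fell for 7 of 15, or 8 adjusted over the list alone, including the malic enzyme Me1 (-5.22) and the haem oxygenase Hmox1 (-2.03; camera adjusted p = 0.00112, and adjusted p = 0.443 with an estimated correlation). Immediate early genes, which cell handling raises, fell for 6 of 19, or 8 adjusted over the list alone (median -0.534, camera adjusted p = 0.0124, and adjusted p = 0.443 with an estimated correlation). The anti-apoptotic gene Bcl2 rose by 1.16 and the fat cell regulator Pparg fell (-5.15). The fatty acid oxidation list that holds Pparg had a median of 0.00565. edgeR called 3061 of 13375 genes, 1615 higher and 1446 lower, but 1997 and 1735 without EYA1+HOXA9 DMSO replicates 2 and 3, and 2000 and 1857 without HOXA9 DMSO replicates 1 and 2. Camera passed 8 of 28 lists.

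In benzarone the same lines differed in 3382 genes, 2027 higher and 1355 lower, and in 2211 without EYA1+HOXA9 benzarone replicate 1. Neutrophil granule genes were lower with EYA1. Elane, neutrophil elastase, stood at 473 ± 39.4 against 3122 ± 119 CPM (-2.72, edgeR adjusted p = 5.48e-08), the myeloperoxidase gene Mpo fell (-2.71), and so did 9 of 14 primary granule genes, also adjusted over the list alone (camera adjusted p = 2.13e-09, adjusted p = 0.0376 with an estimated correlation and 0.0724 with that and the replicate block). Secondary granule genes fell for 12 of 18, or 14 adjusted over the list alone, with Chil3 at -7.16 and the histone deiminase Padi4 at -4.19 (camera adjusted p = 8.26e-14, and adjusted p = 0.255 with an estimated correlation). Glycolysis genes fell for 13 of 17, or 14 adjusted over the list alone, by -0.94 for Eno1 and -0.89 for Gpi1 (camera adjusted p = 7.45e-07, and adjusted p = 0.349 with an estimated correlation). Monocyte genes rose for 13 of 23 and fell for 1, or 14 and 2 adjusted over the list alone, such as the chemokine receptor Ccr2 (2.02) and the lipopolysaccharide receptor Cd14 (1.35; camera adjusted p = 0.00377, and adjusted p = 0.673 with an estimated correlation). Interferon genes rose for 8 of 15, and 8 adjusted over the list alone, with Oasl2 at 4.19 and Irf7 at 1.89 (camera adjusted p = 0.00155, and adjusted p = 0.534 with an estimated correlation). Mitochondrial RNAs were higher for 3 of 13, or 10 adjusted over the list alone (median 0.889, camera adjusted p = 0.0249, and adjusted p = 0.708 with an estimated correlation). They made up 1.72 to 2.43% of counts with EYA1 and 0.835 to 1.67% without, so a difference in cell or RNA quality is not excluded. Hoxa9, vector reads included, was higher by 2.73, the cytokine receptor Flt3 by 4.72 and the class II gene H2-Ab1 by 4.30. Camera passed 13 of 28 lists.

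Benzarone against DMSO in EYA1+HOXA9 cells asked what the compound does in cells that carry EYA1 with HOXA9. Primary granule genes such as Mpo and Elane fell and monocyte and interferon genes rose. Mpo went from 964 ± 617 to 39.4 ± 17.1 CPM (-4.61, edgeR adjusted p = 0.000153) and Elane from 2308 ± 224 to 473 ± 39.4 (-2.29, adjusted p = 2.4e-06), and of 14 primary granule genes 6 fell and 2 rose, or 7 and 2 adjusted over the list alone (camera adjusted p = 0.000499, and adjusted p = 0.349 with an estimated correlation). Of 18 secondary granule genes 4 fell and 1 rose, or 6 and 1 adjusted over the list alone (camera adjusted p = 0.0249, and adjusted p = 0.656 with an estimated correlation). Interferon genes rose for 14 of 15 and fell for 1, also adjusted over the list alone, with the antiviral genes Rsad2 (2.67), Usp18 (2.66) and Xaf1 (2.48; camera adjusted p = 1.16e-07, and adjusted p = 0.349 with an estimated correlation). Of 23 monocyte genes 13 rose and 1 fell, or 14 and 1 adjusted over the list alone (camera adjusted p = 0.000736, and adjusted p = 0.54 with an estimated correlation). The lysosomal glycoprotein gene Gpnmb (2.51), the macrophage receptor gene Adgre1 (2.41) and Ccr2 (2.23) rose among them. Immediate early genes, which cell handling raises, rose for 9 of 19, or 12 adjusted over the list alone (median 1.01, camera adjusted p = 0.00721, and adjusted p = 0.526 with an estimated correlation). DNA repair genes fell for 11 of 26, or 16 adjusted over the list alone, such as Bard1 (-0.93), Rad51ap1 (-0.78) and Exo1 (-0.76; camera adjusted p = 0.00027, and adjusted p = 0.349 with an estimated correlation). Glycolysis genes fell for 10 of 17, or 13 adjusted over the list alone, with Pgk1 at -0.93 (camera adjusted p = 0.00027, and adjusted p = 0.526 with an estimated correlation), and the growth regulator Myc fell (-1.24). Pdk4, a kinase that turns glucose oxidation down, rose from 2.80 ± 2.36 to 134 ± 97.7 CPM (5.56). The endoplasmic reticulum chaperone Hspa5 rose by 1.40, while its list of stress and unfolded protein response genes had a median of -0.393.

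Among the retinal determination genes under benzarone, Eya1 fell from 237 to 155 ± 19.1 CPM (-0.61, edgeR adjusted p = 0.00713), Six4 fell (-1.50) and Dach1 fell (-0.85), 3 of 7 measured and 5 adjusted over the list alone (camera adjusted p = 0.0415, and adjusted p = 0.526 with an estimated correlation). Counts of the introduced Eya1 and of the cells' own cannot be told apart here, and without Eya1 the list did not pass (camera adjusted p = 0.0872). Hoxa9 rose from 382 to 1402 ± 216 CPM (1.87, adjusted p = 9.58e-05), while its cluster neighbours Hoxa10 and Hoxa7 had 0 counts in each of these libraries. edgeR called 3933 genes, 2278 higher and 1655 lower, but 2353 without EYA1+HOXA9 DMSO replicate 3, and camera passed 10 of 28 lists. Changes with benzarone ran against the difference between the lines. Higher in benzarone and lower in EYA1+HOXA9 than in HOXA9 cells in DMSO were 666 genes (246 for independent lists), and 574 went the opposite way (200). Both comparisons share the EYA1+HOXA9 DMSO libraries, so part of the excess may come from them. Unchanged lines had 0 such genes in 20 simulations, which leave out real effects and do not measure that part. The covariance of the effects over genes was -0.376, where the shared DMSO libraries alone gave -0.0708, and at a mean of at least 10 CPM -0.123 against -0.0206. The correlation was -0.311, where the shared libraries alone gave -0.505, and the difference of correlations does not measure a shared effect.

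**Figure D3:**
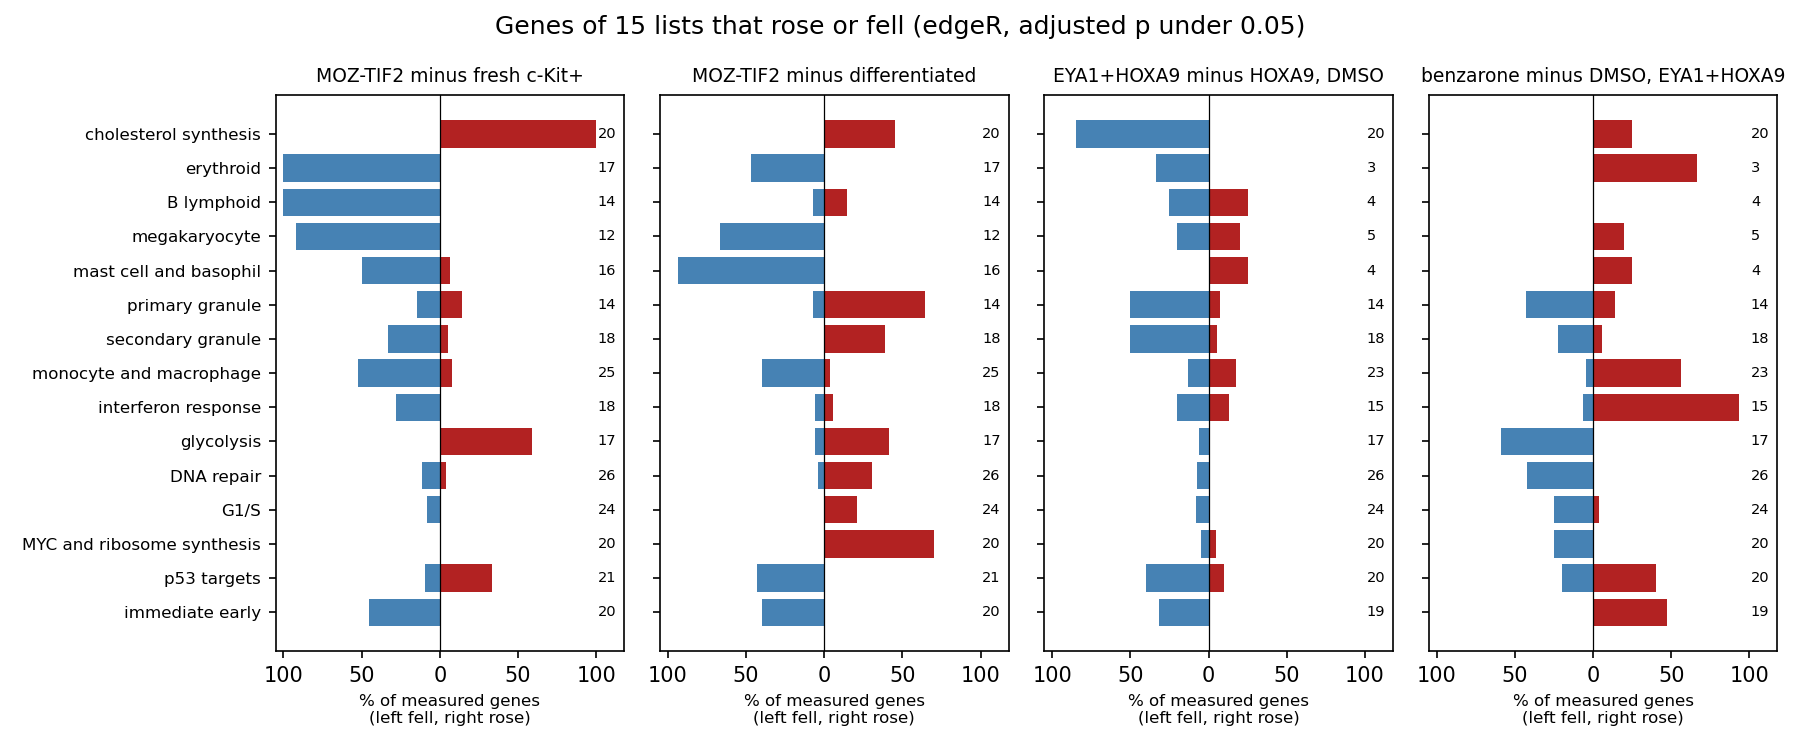
Share of the measured genes of 15 lists that rose (bars to the right) or fell (bars to the left) in 4 bulk comparisons, in percent, with the number of measured genes beside each bar. With benzarone in EYA1+HOXA9 cells 14 of 15 interferon genes rose, and in MOZ-TIF2 against fresh cells all 20 cholesterol synthesis genes rose.

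In HOXA9 cells without EYA1, benzarone gave no gene past the threshold with edgeR, where 232 genes had an unadjusted p under 0.05, DESeq2 called 14 and edgeR with the replicate number as a block 11. Hoxa9 read 211 ± 12.8 against 203 ± 33.1 CPM (0.06). Mpo, which benzarone lowered in EYA1+HOXA9 cells, was lower here too, though not called. It read 209, 300 and 262 CPM in benzarone against 1020, 1210 and 1090 CPM in DMSO. The replicate numbers pair these libraries, and the 11 blocked calls, all higher, held the lipid droplet gene Plin2 (1.04, 457 against 221 CPM), the copper carrier Cp (2.49), the retinal dehydrogenase Aldh1a3 (2.06) and the monocyte regulator Irf8 (0.83). By camera 11 of 28 lists passed, none of them with a member called over all genes. Adjusted over the list alone, and among these 11 lists only, 2 fatty acid oxidation genes and 1 gene each of the stem cell, secondary granule and erythroid lists passed. The p53 targets were higher as a list (median 0.256, camera adjusted p = 1.17e-11, adjusted p = 0.0312 with an estimated correlation and 0.0534 with that and the block). Interferon genes (median 0.448, camera adjusted p = 1.42e-09, adjusted p = 0.0957 with an estimated correlation and 0.05 with that and the block) and monocyte genes (0.436, camera adjusted p = 1.78e-06, and adjusted p = 0.37 with an estimated correlation) were also higher as lists, with 0 members called adjusted over the list alone. Fatty acid oxidation genes (camera adjusted p = 4.82e-07) and BCL2 family genes (0.000712) passed upward and stem cell genes (0.000712) downward, at adjusted p = 0.0362, 0.0362 and 0.0442 with an estimated correlation and 0.101, 0.101 and 0.183 with that and the block. Secondary granule genes passed upward (median 0.407, camera adjusted p = 0.000114, and adjusted p = 0.535 with an estimated correlation), opposite to their fall under benzarone in EYA1+HOXA9 cells (median -0.306). Erythroid genes (3 measured) passed upward at 0.0499 (adjusted p = 0.37 with an estimated correlation). Glycolysis genes (median -0.0959, 0.0153) and mitochondrial RNAs (-0.173, 0.00462) passed downward, each at adjusted p = 0.644 with an estimated correlation. Mast cell genes passed downward at 0.0499 (adjusted p = 0.37 with an estimated correlation) and not with the block (0.0525).

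The benzarone effect itself differed between the lines in 1009 genes by an interaction test in edgeR, 630 more positive and 379 more negative with EYA1. Elane (-2.22, edgeR adjusted p = 0.000127) and Hoxa9 (1.81, adjusted p = 0.0045) were among them. The count was 1687 with the replicate block and 1702 with DESeq2. It was 570 and 541 without EYA1+HOXA9 benzarone replicates 1 and 2, 408 without EYA1+HOXA9 DMSO replicate 3, 667 and 656 without HOXA9 benzarone replicates 2 and 3, and 499 and 588 without HOXA9 DMSO replicates 1 and 2. Across 13375 genes the effects in the lines correlated with Pearson's r of 0.167 and Spearman's rho of 0.275, and across 8898 genes with a mean of at least 10 CPM with 0.357 and 0.371. Genes are not independent replicates here either. Of the 3933 genes called with EYA1, 70% had the same sign without it, at a median size of 0.102 against 0.849 on the log2 scale.

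Single MOZ-TIF2 cells were read on days 1, 3 and 5 of benzarone, with 826 to 1662 cells per condition. Days 1 and 3 had 1 sample per condition, and on day 5 both conditions came from 1 pooled sample, parted by the deposited cell labels, so no difference was tested. Intervals below cover counting error only. On day 1 monocyte chemokine RNA was already higher, with Ccl2 19.9-fold above the 5.94 CPM (5.20 to 6.76) of DMSO, a log2 ratio of 4.31 (4.12 to 4.51). Ppbp, a platelet chemokine (2.13), Arg1, arginase (2.12), Chil3 (1.88) and Plin2 (1.48) were higher as well. Of 19 monocyte genes 15 were higher (median 0.22, above 100% of 10000 random lists matched on level), as were 15 of 19 p53 targets (0.28). Hoxa9 read 206 against 199 CPM (0.05). The median absolute log2 ratio over genes of at least 50 CPM was 0.0875 (2556 genes).

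By day 3 of benzarone, set against DMSO of day 1 since no DMSO of day 3 was read, the median absolute log2 ratio was 0.153 and time and compound differ together. Ppbp stood at 1340 against 28.9 CPM (5.54), Arg1 at 340 against 11.6 (4.87), and the chemokine Ccl7 at 5537 UMIs against 1 (12.5, interval 10.0 to 17.8). All 10 interferon genes (median 2.36), 21 of 22 monocyte genes (1.67) and 18 of 19 p53 targets (0.80) were higher, the last with Cdkn1a, a cell cycle inhibitor, at 1.31. Replication genes (22 of 24, median -0.27), DNA repair genes (23 of 24, -0.33) and ribosome synthesis genes (20 of 20, -0.20) were lower. Meis1 (-0.41) was lower, and Hoxa9 read -0.05, or 0.01 with TMM factors between the summed libraries.

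On day 5, benzarone and DMSO cells differed with a median absolute log2 ratio of 0.708. Macrophage genes were far higher in benzarone, with Arg1 at 1280 against 21.2 CPM (5.91), the lipoprotein lipase Lpl at 5.48, the transcription factor Maf at 5.42, and Plin2 at 1190 against 97.6 CPM (3.61). Mpo was lower at 88.0 against 1890 CPM (-4.42), the serine synthesis enzyme Phgdh at -2.89 and the progenitor transcription factor Myb at -1.90. The leukaemia homeobox genes were lower too, Meis1 at 2.41 against 26.3 CPM (-3.45) and Hoxa9 at 82.3 against 204 (-1.31). Interferon genes (17 of 17, median 4.14), monocyte genes (23 of 24, 3.89), secondary granule genes (18 of 18, 1.72) and p53 targets (18 of 21, 1.07) were higher. Lists of other lineages went both ways. Higher were megakaryocyte genes with a median of 3.90 (3 of 5 higher, 0.745% against 0.0219% of UMIs, most of them Ppbp and Pf4) and dendritic cell genes with 1.68 (4 of 5). Mast cell genes (6 of 7, -1.45) and B-lymphoid genes (2 of 3, -1.23) were lower, though the B-lymphoid share of UMIs was 0.00127% in benzarone against 0.00101%. Immediate early genes, which cell handling raises, were higher (17 of 18, 1.20). Ribosome synthesis genes (20 of 20, -1.53), replication genes (24 of 24, -1.10), mitosis genes (23 of 24, -0.90) and DNA repair genes (25 of 26, -0.98) were lower. TMM factors moved the median of all genes by 0.11, so each ratio may be read against that shift, and in 20 of 28 lists the median had the sign it had in the EYA1+HOXA9 line, as it did in 20 of 28 for the HOXA9 line. On day 1 the signs were the same in 11 and 13 of 24 lists and on day 3 in 14 of 24 for either line.

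**Figure D4:**
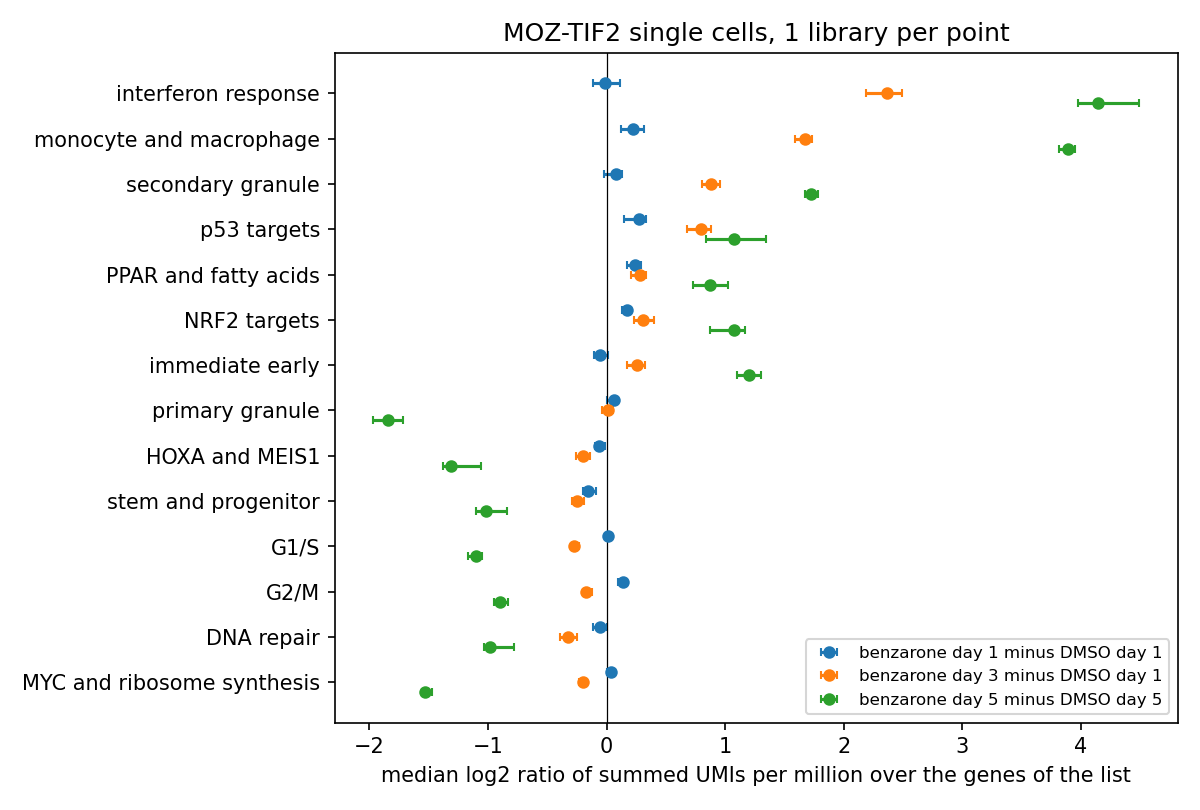
Median log2 ratio of summed UMIs over the genes of each of 14 lists in single MOZ-TIF2 cells, benzarone over DMSO, on days 1, 3 and 5 (day 3 against DMSO of day 1), with 95% intervals from Poisson resampling that cover counting error only. The monocyte list goes from 0.22 on day 1 to 1.67 on day 3 and 3.89 on day 5.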

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

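The tests of technical explanations and the splits of the libraries given here were chosen only after the results had been seen. The results are listed because the benzarone effect differed between the EYA1+HOXA9 and HOXA9 lines by the interaction test, in 1009 genes and in 56 named genes. Values are the log2 effect with EYA1 minus that without it. Positive differences were found for Hoxa9 (1.81), Pbx3 (0.867), Akap2 (4.57), Erbb3 (4.18), Mical2 (4.03), Fam213a (3.92), Vcam1 (3.66) and Akap12 (3.6). The monocyte genes Adgre1 (2.03), Gpnmb (1.92), Ccr2 (1.67) and Cd14 (1.25) and the interferon genes Xaf1 (1.95), Isg15 (1.79) and Irf7 (1.42) were more positive too. The immediate early genes Jun (1.90), Klf2 (1.52) and Klf6 (0.924) followed, as did the p53 targets Plk2 (1.69) and Sesn1 (1.39), the stress genes Creld2 (1.31), Sdf2l1 (1.01), Srxn1 (0.972) and Fth1 (0.967). The rest were Itgb3 (1.44), Cyp11a1 (1.30), Insig1 (1.13), Blvrb (0.908) and Kif23 (0.789).

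More negative with EYA1 were the granule genes Nkg7 (-3.46), Mpo (-2.50), Elane (-2.22), Cxcr2 (-2.17), Padi4 (-2.10), Wfdc21 (-2) and Prss57 (-1.14), and Zfyve9 (-5.25), Nebl (-5.00), Kcnq5 (-4.17), Slc32a1 (-4.10), Hlf (-4.07) and Chst15 (-3.92). Sobp was more negative too (adjusted p = 0.0489), without counts in HOXA9 cells in DMSO, so its size is open. The BCL2 family genes Bcl2a1d (-3.29), Bcl2a1b (-2.76), Bcl2a1a (-1.46) and Bcl2l1 (-0.949) belong here. Bcl2a1a, Bcl2a1b and Bcl2a1d are near-identical copies, so their values are uncertain. Further ones were Acot1 (-3.33), Myc (-1.17), Ifit2 (-1.09), Ccne2 (-0.954), Bard1 (-0.92), Decr1 (-0.813), Exo1 (-0.716), Rad51ap1 (-0.693) and Kif11 (-0.461). Of the 56 named genes 20 stayed past the threshold in every setting run, Hoxa9, Elane and Zfyve9 among them, and 36 ended without at least 1 library. The most calls ended without EYA1+HOXA9 DMSO replicate 3 (31), HOXA9 DMSO replicate 1 (31) and EYA1+HOXA9 benzarone replicate 1 (28).

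As lists, interferon genes (median difference 1.61, camera adjusted p = 0.000263, and adjusted p = 0.465 with an estimated correlation), immediate early genes (0.924, 0.000407, and adjusted p = 0.465 with an estimated correlation), monocyte genes (0.64, 0.0207, and adjusted p = 0.625 with an estimated correlation) and oxidative stress genes (0.36, 0.0499, and adjusted p = 0.608 with an estimated correlation) were more positive. Secondary granule genes (-0.90, 0.000263, and adjusted p = 0.608 with an estimated correlation), primary granule genes (-0.458, 0.000407, and adjusted p = 0.205 with an estimated correlation) and DNA repair genes (-0.374, 0.000407, and adjusted p = 0.437 with an estimated correlation) were more negative. So were BCL2 family genes (-0.322, 0.0141, and adjusted p = 0.205 with an estimated correlation). Glycolysis genes were more negative as a list too (-0.488, 0.00112, and adjusted p = 0.608 with an estimated correlation), though none of them is among the named genes.

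An equal benzarone effect hidden by the larger spread of the HOXA9 libraries would give a slope near 1 of the HOXA9 changes on the EYA1+HOXA9 changes. The slope over 2606 called genes with a mean of at least 10 CPM was 0.112 (0.0935 to 0.133). Simulated equal effects gave at least 0.972, but they were built on the fitted EYA1+HOXA9 changes, which fixes a slope near 1. The genes were chosen by their calls with EYA1, which lowers the slope by an amount that was not measured. So the slope alone does not settle that explanation. These genes had a median absolute log2 change of 0.0775 in HOXA9 cells against 0.648 with EYA1. Median SDs of log2 CPM in benzarone and DMSO were 0.198 and 0.159 for HOXA9 against 0.158 and 0.128 with EYA1. The gap is larger than these spreads, so for these genes as a set the values argue against that explanation. The choice between TMM and DESeq2 size factors does not account for the interaction calls, since the latter called 998 genes. Both assume that most genes do not change, so a shift shared by most genes was not tested. Of 100 divisions drawn for the interaction 12 called as many as the real 1009, so chance was not excluded this way, with up to 3755 genes. All 12, the real one among them, keep the real division of the EYA1+HOXA9 libraries, and other divisions of these called at most 2. Every drawn division that keeps it called at least 1009 genes, however the HOXA9 libraries were divided. So the count follows the benzarone effect of the EYA1+HOXA9 line, and these divisions do not show that the lines differ.

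The rise of Hoxa9 counts with benzarone in the EYA1+HOXA9 line (1240 to 1650 CPM against 314 to 506) may come from reads of the HOXA9 vector, since the neighbours Hoxa10 and Hoxa7 had 0 counts in the benzarone libraries. That test is weak, because Hoxa10 had none in the HOXA9 line either, and Hoxa9 did not pass in that line, which was made with a HOXA9 vector too. The choice between TMM and DESeq2 size factors does not account for the rise, which was 1.86 with the latter. Whether the vector or the gene itself responds stays open.

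Each comparison of 3 against 3 libraries has 10 splits, too few for a share under 0.05. The real split called 3061 genes for the lines in DMSO and the highest other 0, 3382 and 0 in benzarone, 3933 and 1 for benzarone with EYA1, and 0 and 4 for benzarone with HOXA9. There the numbers pair the libraries, and the highest other split that parts 3 pairs called 0.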

How the results depend on the processing

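Settings added after seeing the data were the peak lists of single replicates, peaks over the gene span, the comparisons within groups of like level, the single-cell settings for the list signs, the retinal determination list without Eya1, and the overlap without each library. Of 7470 values under another setting, 6540 of the single-gene and list values stayed on their side. Among the other single-gene and list values 666 were weaker, 109 moved past a set margin, 10 were stronger and 1 reversed. Among the counts and main values 99 stayed, 33 were weaker, 8 moved past a set margin and 4 were stronger. Among named genes, 3070 of 3212 values kept direction and call under settings that leave out no library, 136 lost the call, 6 gained it and 0 reversed, and with 1 library left out 2851 of 3379 kept both. Hoxa10 in differentiated against fresh cells read 1.89 without differentiated replicate 1 and reversed to -8.08 without replicate 2. It had not passed before, and replicate 2 alone held its counts. With each library left out, called genes ranged from 374 to 3181 for MOZ-TIF2 against fresh, 2847 to 4278 for MOZ-TIF2 against differentiated, 1259 to 4891 for differentiated against fresh, 1735 to 3486 and 2211 to 3596 between the lines in DMSO and benzarone, 2353 to 3923 and 0 to 1 for benzarone with EYA1 and with HOXA9, and 408 to 1182 for the interaction. A group left with 1 library is assumed to vary like the others, and the fewer samples are part of the cause. The replicate block gave 2094 genes for MOZ-TIF2 against fresh, 11 for benzarone with HOXA9 and 1687 for the interaction, with the other counts within 1.5 times, and DESeq2 gave 14 and 1702 for the last of these. In the c-Kit table same-numbered libraries did not deviate together (correlations -0.0082, -0.051 and -0.076), nor did those of the EYA1+HOXA9 line (-0.0025, -0.065 and 0.0082), and not every library in that line correlated best with its own number. In the HOXA9 line the block changed no call but those given with that comparison. With an estimated correlation the lists that passed went from 16 to 3 for MOZ-TIF2 against fresh, 20 to 0 against differentiated, 16 to 0 for differentiated against fresh, 8 to 1 and 13 to 1 between the lines, 10 to 0 and 11 to 4 for benzarone with EYA1 and with HOXA9, and 9 to 0 for the interaction. By fry 10 passed for MOZ-TIF2 against differentiated, 0 for benzarone with HOXA9 and 5 for the interaction. Genes higher in MOZ-TIF2 than in both c-Kit+ groups went from 588 to 38 and 58 without fresh replicates 1 and 2 and 461 and 423 without differentiated replicates 1 and 2, and 599 and 397 without MOZ-TIF2 replicates 1 and 2. The odds ratio of peaks at higher genes was 1.01 with peaks found in replicate 1 alone and 0.992 within groups of like level in MOZ-TIF2 cells. At a mean of at least 10 CPM the correlation of benzarone effects went from 0.167 to 0.357. The covariance with the difference between the lines went from -0.376 to -0.123 there. In single cells the median absolute ratio of day 3 was 0.172 as a mean over cells and 0.137 with TMM factors (0.153 in sums), and that of day 5 was 0.723 and 0.654 (0.708). Except where a smaller number of genes or samples is named, the cause was not tested. The stronger part of the peaks and the strongest 10 peaks were not run, since the lists give no scores. Depth limits the fresh libraries most, at 12397486 and 15550960 counts.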

Other observations

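The tests of peaks against gene level and of the replicate 1 list were chosen only after the result had been seen. Differentiated replicate 2 held low counts of granulocyte and MOZ-TIF2 genes that replicate 1 nearly lacked. Mpo stood at 99.9 CPM against 0.0955 in replicate 1, Prtn3 at 36.1 against 0.478, Elane at 24.7 against 0 and Hoxa10 at 5.08 against 0. Over 28 genes that were low in replicate 1 and high in MOZ-TIF2 cells, replicate 2 held 1.72% of the MOZ-TIF2 level when pooled, with a median of 1.41% and a highest value of 7.06% for Ak4. The shares spread beyond a common ratio, with 67.9% of the genes outside the 99% counting range.

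DESeq2 called 14 genes for benzarone in HOXA9 cells, 11 higher and 3 lower. Chil3 stood at 856 against 311 CPM (1.46) and Plin2 at 457 against 221 (1.04), while the interferon-induced membrane gene Ifitm1 was lower at 168 against 379 (-1.18). Chil3 and Ifitm1 were not called by edgeR and Plin2 only with the block, and these 3 were picked after their values were seen. On day 5 of benzarone in single cells haem oxygenase Hmox1 (3.97) and ferritin Fth1 (2.98), also picked after their values were seen, were higher, and 7 of 7 aryl hydrocarbon receptor genes had a median of 2.62. Respiratory chain genes were lower in 17 of 18 (-0.59) on that day, where random lists of like level had a median of -0.325 and 9.48% of them lay lower, so the list is not set apart. In benzarone, EYA1+HOXA9 cells held more RNA of 4 of 6 dendritic cell genes than HOXA9 cells, also adjusted over the list alone (camera adjusted p = 0.00485, and adjusted p = 0.322 with an estimated correlation).

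Genes higher in MOZ-TIF2 than in fresh c-Kit+ cells more often had a Ty1 peak, and the level of a gene in MOZ-TIF2 cells is a candidate explanation. Within 10 groups of like level in MOZ-TIF2 cells the odds ratio was 0.992 (0.879 to 1.12), which goes with that explanation. Within groups of like mean level over all 6 libraries it was 1.42 (1.26 to 1.6), so level over all libraries does not account for the whole excess. Within groups of like level in fresh cells it was 2.48 (2.19 to 2.8), and in differentiated cells 1.51 (1.34 to 1.69). The replicate 1 list, which does not use replicate 2, gave 2 (1.8 to 2.22), so the excess is found without the replicate 2 list. Of its 3676 peaks 3303 overlap replicate 2 peaks, and those found in replicate 1 alone gave 1.01 (0.749 to 1.36). Peaks found in replicate 2 alone gave 1.2 (1.01 to 1.41). The excess was thus largest in peaks that both lists hold, and a part of the antibody in it cannot be told. Binding that raises a gene would also place the bound genes at a high level in MOZ-TIF2 cells, so cause and effect cannot be parted here and no biological explanation was tested.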
